A study of Homo sapiens with 12 samples.

How the data were processed

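HEL is an established human erythroleukaemia cell line with an activating JAK2 mutation, and the labels call it an erythroblast line. Cells were treated for 6 h with the vehicle DMSO, with SBI-0206965 or with ULK101, both inhibitors of the autophagy kinase ULK1, and 4 libraries were made per group, 12 in all. The series' design text gives a dose of 5 µM for both inhibitors, while the treatment protocol of the samples gives the same figure in mM, so the unit of the dose rests on the design text. Per the labels' protocols, the 4 replicates of a group were plated as biological replicates, poly-A RNA was made into stranded libraries, and these were sequenced in paired-end mode on a NovaSeq.

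Per the submitters' processing notes, the authors used FastQC, Trimmomatic, STAR, HTSeq and edgeR with the genome build hg38. Versions, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. The deposited table holds 14520 genes, with CPM (reads of a gene scaled by the library's total) per library as made by the authors, and the log2 fold change, mean log2 CPM, p-value and adjusted p-value of the authors' own comparison of both inhibitors together against DMSO. From the values, every gene exceeded 1 CPM in at least 2 libraries, so genes below that level were not analysed here. The CPM were relative to each library's total of counted reads and carried no further scaling. In the file 19 gene symbols had been turned into dates by a spreadsheet, and these genes were named by their Ensembl ID. A further 112 genes were named from a reference table, and 211 genes kept an ID only. Symbols are those of the file, some of them older ones.

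Whole reads could be recovered from the deposited CPM: 100% of the values in every library came out within 0.01 of a whole number. The totals ran from 43597555 reads (DMSO replicate 2) to 62495111 (DMSO replicate 4), and a gene with 0 reads has an upper limit of 0.048 to 0.0688 CPM (3 reads). These limits cover counting error only. Because the deposited unit is CPM, the count test planned before the data were examined was replaced by the test planned for that case. The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(CPM + 1) after TMM scaling (edgeR 4.0.16), with all 12 libraries in 1 fit of 3 groups and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Means and SDs are of TMM-scaled CPM, with n = 4 per group. The low-count filter of edgeR removed 0 genes. The comparisons were each inhibitor against DMSO, the mean of both against DMSO, ULK101 against SBI-0206965, and the genes changed by both inhibitors.

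For 29 gene lists, camera of limma was run on the same log values with a preset correlation of 0.01, and again with a correlation estimated from the data. The rotation test fry, also of limma, was run beside it, and members were counted after adjustment over all genes and adjusted over the list alone. The genes named in the text follow a rule: ULK1 and ULK2 in each comparison; the 10 largest rises and the 10 largest falls per inhibitor against DMSO, in both inhibitors together and between the inhibitors, among genes past the threshold with a mean of at least 5 CPM and with all libraries of one group beyond all of the other; and per list described up to 4 members with the lowest p and 1 member of the other direction. Groups, tests, lists, this rule and the first set of other settings below were fixed before the data were examined.

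The tests were run on simulated data first, with counts drawn for the 14520 genes from their real means, library sizes and spread. For SBI-0206965 against DMSO, limma-trend recovered 56.7% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold, and 8 unchanged genes passed. For ULK101 against DMSO the shares were 62.7%, 82.1% and 92.4%, and 6 unchanged genes passed. Each share rests on 66 or 67 genes, so small gaps between the inhibitors carry no weight. Far fewer genes were changed in the simulation than passed in the real data. The adjusted threshold was therefore stricter there, and the shares do not carry over to the real comparisons.

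The settings fixed beforehand were DESeq2 1.42.0 and limma-voom on the recovered reads, median-of-ratios (RLE) scaling, no low-count filter, a stricter filter of at least 1 CPM in 4 libraries, other pseudocounts, only the groups compared in the fit, the replicate number as a block, a 2-fold minimum, and each library left out in turn. Settings chosen after seeing the data were the quasi-likelihood test of edgeR on the recovered reads, the CPM as deposited without TMM scaling, the libraries numbered 4 left out or given their own term, and the removal of each library's trend on GC content and gene length (natural splines with 4 degrees of freedom). GC content and length came from GENCODE release 29 transcripts, which held a value for 99.0% of the genes. The quasi-likelihood test on the recovered reads called 896 genes for SBI-0206965, 2780 for ULK101, 1677 for the mean of both, and 2502 between the inhibitors. Coordinates are those of the deposited table, in hg38.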

Results

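The transcriptomes of 12 HEL cultures were compared after 6 h with DMSO, SBI-0206965 or ULK101 (5 µM by the series' design text, 4 libraries per group). Values are TMM-scaled CPM, and fold changes are log2 differences on the log2(CPM + 1) scale with their standard error (SE). Library totals ran from 43597555 to 62495111 reads. The first principal component held 33.2% of the variance and parted the ULK101 libraries from the other 8. The second held 18%, and within each group the library numbered 4 had its highest value. The replicates of a group were separately plated cultures of 1 cell line, so p-values measure the spread between the libraries of such cultures. That spread includes the shift of the libraries numbered 4 described below, for which the main fit has no term.

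**Figure D1:**
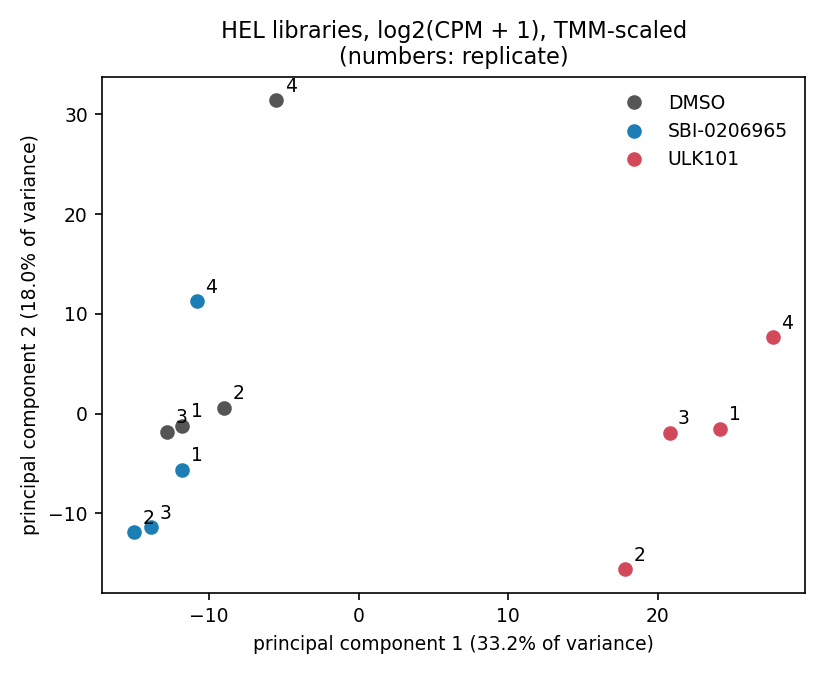
Position of the 12 libraries on the first (x axis, 33.2% of variance) and second (y axis, 18%) principal components of log2(CPM + 1), coloured by group and numbered by replicate. The ULK101 libraries sit between 17.8 and 27.7 on the first component and all others below 0; DMSO replicate 4 sits at 31.4 on the second.

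ULK1, the kinase that starts autophagosome formation and the named target of both inhibitors (hg38 chromosome 12, 131894651 to 131923167, plus strand), was expressed at 45.8 ± 3.63 CPM in DMSO, 48.5 ± 3.75 in SBI-0206965 and 54.8 ± 5.47 in ULK101 (SD, n = 4). Its log2 fold change was 0.08 for SBI-0206965 (adjusted p = 0.66) and 0.25 for ULK101 (adjusted p = 0.0479). It was 0.17 for the mean of both (adjusted p = 0.163) and 0.17 between the inhibitors (adjusted p = 0.192). The rise with ULK101 did not pass when DMSO replicate 1, 2 or 3, SBI-0206965 replicate 1 or 2, or ULK101 replicate 1, 2 or 3 was left out (adjusted p 0.0605 to 0.144), nor with limma-voom (0.0573), median-of-ratios scaling (0.0513) or only the groups compared in the fit (0.0699). Its related kinase ULK2 was at 1.83 ± 0.803 CPM in DMSO and 1.92 ± 0.554 in ULK101. The log2 fold changes of ULK2 were 0.09 for SBI-0206965 (adjusted p = 0.867), 0.07 for ULK101 (adjusted p = 0.866), 0.08 for the mean of both (adjusted p = 0.841) and -0.02 between the inhibitors (adjusted p = 0.957).

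The first comparison asks which genes changed with SBI-0206965 against the vehicle. The largest falls were in EGR1 and ETV5, transcription factors induced by ERK signalling. EGR1, an immediate early gene, was at 64.3 ± 27.5 CPM in DMSO and 16.0 ± 11.1 in SBI-0206965 (log2 fold change -2.13, adjusted p = 0.00362). In every group its replicates 1 and 2 lay above replicates 3 and 4 (DMSO, 70.9 and 100.4 against 42 and 43.8 CPM). The main fit has no term for this, so it is part of the SDs given. The ETS factor ETV5 (chromosome 3, 186046308 to 186110318) fell from 41.8 ± 2.82 to 10.0 ± 1.16 CPM (-1.96, SE 0.091, adjusted p = 3.53e-10), and the ERK phosphatase DUSP6 from 13.6 ± 2.26 to 3.31 ± 0.763 CPM (-1.76, adjusted p = 1.49e-06). Rises were smaller, and the enzyme of haem synthesis ALAD (chromosome 9, 113386317 to 113401333) went from 32.7 ± 3.02 to 60.1 ± 2.44 CPM (0.86, adjusted p = 2.12e-06).

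The other falls named by the rule were WNT11, a secreted ligand, at -1.85, the scaffold protein AKAP12 at -1.77 and the platelet collagen receptor GP6 at -1.74. Cyclin D1 (CCND1) was at -1.65, the phospholipase PLCH1 at -1.61, the Notch target HES1 at -1.59 and the phosphatase UBASH3B at -1.53, with adjusted p of at most 0.000118 for each. The other rises were EXOC3L4 at 1.01, PARK2 (parkin) at 0.90, the cathepsin CTSV at 0.78 and NBPF1 at 0.75. Smaller rises were IQGAP3 at 0.73, DNHD1 at 0.73, NLGN1 at 0.72, ALDH6A1 at 0.72 and POF1B at 0.71. NBPF1 belongs to a family of near-identical copies, so its value is uncertain. EXOC3L4, PARK2 and CTSV lay under 7 CPM in all groups.

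The list of ERK feedback and immediate early genes fell as a group after SBI-0206965: 12 of 20 measured members fell and 0 rose over all genes tested (15 and 0 adjusted over the list alone; camera, adjusted p = 5.03e-19, and adjusted p = 9.28e-05 with an estimated correlation). Beside EGR1, ETV5 and DUSP6, ETV4 fell from 41.0 to 20.1 CPM and FOSL1 from 19.9 to 9.93 CPM. The list of ribosome biogenesis and MYC targets fell with 17 of 30 members down and 0 up (24 and 0 adjusted over the list alone; adjusted p = 1.72e-18, and 0.00454 with an estimated correlation). The processing factors RRP12 (-0.41) and MYBBP1A (-0.48) were among them. Chaperones of the endoplasmic reticulum fell in 10 of 19 members and rose in 0 (12 and 0 adjusted over the list alone; adjusted p = 2.83e-12, and adjusted p = 0.0122 with an estimated correlation). HSPA5 (BiP) went from 817 to 494 CPM and HSP90B1 from 1090 to 712 CPM. Cytosolic heat shock genes fell in 6 of 15 members and rose in 0 (10 and 0 adjusted over the list alone; adjusted p = 2.34e-08, and 0.00454 with an estimated correlation). CHORDC1 was at -0.41 and HSPA8 at -0.33. Megakaryocyte genes fell in 5 of 19 members and rose in 2 (6 and 3 adjusted over the list alone; adjusted p = 0.000191, and 0.0122 with an estimated correlation). GP6 and the integrin subunit ITGB3 (-0.63) fell, and the platelet tubulin TUBB1 rose (0.62).

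The calls of 9 further lists were lost in the setting of camera with an estimated correlation. For the lysosomal genes the estimate was -0.017, below the preset 0.01, so a higher correlation does not account for that loss. JAK-STAT5 targets fell in 9 of 15 members and rose in 0 (11 and 1 adjusted over the list alone; adjusted p = 1.30e-11, but adjusted p = 0.0588 with an estimated correlation). The kinase PIM1 (648 to 421 CPM, -0.62) and the anti-apoptotic BCL2L1 (234 to 151 CPM, -0.62) fell with them. Lower after SBI-0206965 by the preset test were also NF-kB and inflammatory genes (3 of 17 down, 8 adjusted over the list alone, adjusted p = 0.06 with an estimated correlation) and profibrotic and inflammatory secreted factors (3 of 9 down, 4 adjusted over the list alone, adjusted p = 0.0588 with an estimated correlation). The same held for ATF4 and integrated stress response genes (5 of 28 down and 1 up, 5 and 2 adjusted over the list alone, adjusted p = 0.0646 with an estimated correlation), the BCL2 family (2 of 12 down, 4 adjusted over the list alone, adjusted p = 0.121 with an estimated correlation) and HIF targets (2 of 20 down and 1 up, 4 and 1 adjusted over the list alone, adjusted p = 0.532 with an estimated correlation). IL1B (-0.59) and VEGFA (-0.68) fell among the secreted factors. Higher by the preset test were G2/M genes (1 of 24 up, HMMR at 0.38, and 2 adjusted over the list alone; adjusted p = 0.0711 with an estimated correlation), erythroid genes (4 of 28 up, 7 adjusted over the list alone, adjusted p = 0.206 with an estimated correlation) and lysosomal genes (2 of 32 up, 2 adjusted over the list alone, adjusted p = 0.06 with an estimated correlation). Among the erythroid members were FECH, an enzyme of haem synthesis, at 0.42 and the mitochondrial iron importer SLC25A37 at 0.34. The preset calls of HIF targets without DMSO replicate 2 (adjusted p = 0.0865) or SBI-0206965 replicate 4 (0.0509), of lysosomal genes without DMSO replicate 2 (0.0618) and of the BCL2 family without DMSO replicate 4 (0.0543) were lost. That of HIF targets was also lost without all libraries numbered 4 (camera, adjusted p = 0.0744), a setting chosen after seeing the data. Autophagy machinery did not pass (1 of 35 up, 0 adjusted over the list alone, camera adjusted p = 0.307, fry adjusted p = 0.0949). With fry the erythroid genes (adjusted p = 0.051) and HIF targets (0.155) did not pass, and the 5 measured monocyte and macrophage genes passed as lower (0.00699; camera, 0.492; 0 members past the threshold).

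In all, 404 genes rose and 532 fell after SBI-0206965 of 14520 tested (limma-trend, adjusted p under 0.05), and of these 1 rose and 32 fell at least 2-fold. With unscaled CPM 518 rose and 475 fell, and without the libraries numbered 4 672 rose and 873 fell, both chosen after seeing the data. The count dropped to 586 without DMSO replicate 1, 594 without DMSO replicate 3, and 567, 569 and 557 without SBI-0206965 replicates 1, 2 and 3.

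The next comparison asks the same of ULK101. THBS1, the secreted matrix protein thrombospondin 1 (chromosome 15, 39581079 to 39599466), rose from 21.9 ± 2.70 to 512.9 ± 70.4 CPM (log2 fold change 4.49, SE 0.103, adjusted p = 4.26e-15). AKAP12, which fell with SBI-0206965, rose from 19.4 ± 4.56 to 172.1 ± 38.8 CPM with ULK101 (3.08, adjusted p = 1.99e-10; chromosome 6, 151239999 to 151358557). DDIT4, a stress-induced repressor of mTORC1, rose from 13.4 ± 4.87 to 89.3 ± 15.7 CPM (2.69, adjusted p = 4.18e-08). ID3 (chromosome 1, 23557918 to 23559794), an inhibitor of bHLH transcription factors and a BMP target, fell from 8.93 ± 1.70 to 0.319 ± 0.0666 CPM (-2.90, adjusted p = 3.26e-10).

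Further rises were the water channel AQP2 at 3.25, the guanylate-binding proteins GBP5 at 3.10 and GBP4 at 2.48. Others were the retinol dehydrogenase RDH10 at 2.71, ARHGAP29 at 2.68, the cytokine LIF at 2.59 and osteopontin (SPP1) at 2.52. SPP1 was near the floor in DMSO, at 0.0953 CPM against 5.29 with ULK101. Further falls were SMAD6, the inhibitory SMAD of BMP signalling, at -1.62 (101.9 ± 18.8 to 32.3 ± 2.97 CPM), the chemokine receptor DARC (ACKR1) at -1.40 and UNC5B at -1.39. ID1 was at -1.28, the thromboxane receptor TBXA2R at -1.27, the apelin receptor APLNR at -1.26, KAZN at -1.25, FOSL1 at -1.14 and ID2 at -1.13, with adjusted p of at most 4.03e-05 for each.

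Genes of ATF4 and the integrated stress response rose together after ULK101: 20 of 28 members rose and 1 fell (23 and 1 adjusted over the list alone; camera, adjusted p = 3.86e-14, and 0.00134 with an estimated correlation). ATF4 itself went from 324 to 491 CPM (0.60), the serine synthesis enzyme PSAT1 from 74.9 to 130 CPM (0.79) and PCK2 from 32.7 to 63.8 CPM (0.94), while the member that fell was the pseudokinase TRIB3 (-0.22). Ribosome biogenesis and MYC targets fell in 24 of 30 members and rose in 0 (26 and 0 adjusted over the list alone; adjusted p = 6.13e-16, and 0.00875 with an estimated correlation). MYC went from 747 to 496 CPM (-0.59), MYBBP1A was at -0.74, NOP14 at -0.45 and NOP58 at -0.51. G2/M and mitosis genes fell in 12 of 24 members and rose in 0 (20 and 0 adjusted over the list alone; adjusted p = 5.34e-12, and 0.0129 with an estimated correlation). The mitotic kinase PLK1 was at -0.67, CDC20 at -0.61, KIF20A at -0.69 and BUB1 at -0.67.

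The calls of 4 lists rested on the preset setting of camera. Erythroid genes fell in 12 of 28 members and rose in 0 (15 and 1 adjusted over the list alone; adjusted p = 4.18e-05, but adjusted p = 0.17 with an estimated correlation). HEMGN was at -0.71, the spectrin SPTB at -0.52 and the factor NFE2 at -0.46. JAK-STAT5 targets fell in 7 of 15 members and rose in 2 (8 and 3 adjusted over the list alone; adjusted p = 0.00244, but adjusted p = 0.498 with an estimated correlation). PIM2 fell by 0.86 on the log2 scale and PIM1 by 0.44, and the cytokine OSM rose (1.01). Cytosolic heat shock genes fell in 6 of 15 members (8 adjusted over the list alone; adjusted p = 0.0101, but adjusted p = 0.153 with an estimated correlation) and chaperones of the endoplasmic reticulum in 3 of 19 (4 down and 1 up adjusted over the list alone; adjusted p = 0.031, but adjusted p = 0.498 with an estimated correlation). The chaperone call was also lost without DMSO replicate 1 (adjusted p = 0.0854), DMSO replicate 3 (0.0832), ULK101 replicate 1 (0.0616) or ULK101 replicate 4 (0.0525).

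Autophagy machinery rose in 8 of 35 members and fell in 0 (8 and 0 adjusted over the list alone), among them the ATG8 family member GABARAPL1 at 0.87 and the phosphoinositide effector WIPI1 at 0.40, and the list passed with fry (adjusted p = 0.00521), which does not compare it with other genes, but not with camera (adjusted p = 0.246). ERK feedback and immediate early genes went both ways, with 4 of 20 up and 7 down (4 and 10 adjusted over the list alone). SPRY1 (0.89) and EGR3 (1.48) were among those that rose, with EGR3 near the floor in DMSO (0.113 to 0.535 CPM). The list did not pass with camera (adjusted p = 0.359) and passed as lower with fry (adjusted p = 0.0455). Megakaryocyte genes likewise had 3 of 19 members up and 5 down (3 and 5 adjusted over the list alone; adjusted p = 0.614), with a median of -0.04 and a mean of 0.12, and THBS1 is on this list. NF-kB genes had 4 of 17 up, NFKB2 (0.74) and TNFAIP3 (0.58) among them, and 1 down (4 and 1 adjusted over the list alone; camera, adjusted p = 0.381; fry, higher, 0.0447). Monocyte and macrophage genes (5 measured members, adjusted p = 0.898) and lymphoid and stromal markers (6 measured members, adjusted p = 0.912), which stand for other cell types, did not pass.

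**Figure D2:**
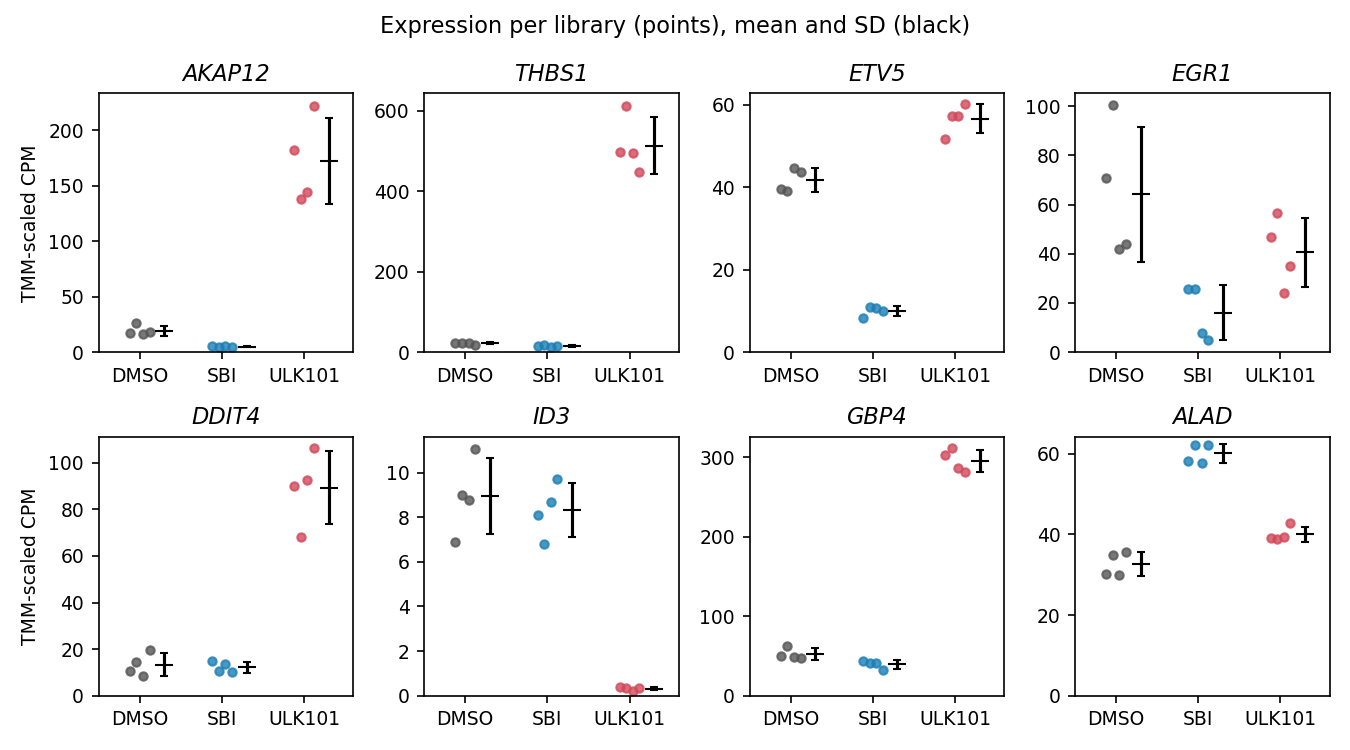
TMM-scaled CPM (y axis, linear) of 8 genes in DMSO, SBI-0206965 (SBI) and ULK101, 1 point per library, with the group mean and SD in black (n = 4). AKAP12 and ETV5 lie below DMSO with SBI-0206965 and above it with ULK101, and ID3 averages 0.319 CPM with ULK101 against 8.93 in DMSO.

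In total 1434 genes rose and 1421 fell after ULK101 (limma-trend), of which 98 rose and 18 fell at least 2-fold. With the deposited CPM left unscaled 1971 rose and 957 fell, and with the trends on GC content and length removed 1708 rose and 2836 fell, both chosen after seeing the data. With median-of-ratios scaling 1393 rose and 1468 fell. The balance of directions thus rests on the processing. Without the libraries numbered 4, 1862 rose and 2064 fell.

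The genes lowered by both inhibitors with the largest smaller change were TBXA2R (-1.04 with SBI-0206965 and -1.27 with ULK101), the cytokine receptor IL21R (-0.99 and -1.13), FOSL1 (-0.94 and -1.14) and the aquaglyceroporin AQP3 (-1.41 and -0.86). Then came CD24 (-1.29 and -0.86), MYCN (-0.78 and -0.80), CCND1 (-1.65 and -0.77), BCRP3 (-0.82 and -0.75), PLVAP (-0.72 and -1.04) and KAZN (-0.70 and -1.25). Raised by both were NBPF1 (0.75 and 0.92), DNHD1 (0.73 and 0.91), ALDH6A1 (0.72 and 0.75), TRIM66 (0.65 and 0.67) and SHF (0.62 and 0.90). Smaller shared rises were HERC2P4 (0.61 and 1.02), the deacetylase HDAC11 (0.58 and 0.72), the repressor GFI1 (0.57 and 1.68), the lysosomal membrane protein SCARB2 (0.57 and 0.60) and SESN3 (0.55 and 0.70). BCRP3, HERC2P4 and NBPF1 have near-identical copies, so their values are uncertain.

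The SBI-0206965 calls of 4 of these raised genes depended on single libraries or on the setting. HDAC11 did not pass without any 1 of the 4 DMSO or 4 SBI-0206965 libraries or without ULK101 replicate 1 or 3 (adjusted p 0.058 to 0.134), nor with limma-voom (0.0908) or a pseudocount of 5 (0.0552). SHF was lost without DMSO replicate 2 (0.0914), SBI-0206965 replicate 1 (0.0733) or SBI-0206965 replicate 4 (0.0813). Without all libraries numbered 4, a setting chosen after seeing the data, SHF (0.0807) and HDAC11 (0.0564) were lost too. GFI1 was lost without DMSO replicate 1 (0.0566), DMSO replicate 3 (0.0527) or SBI-0206965 replicate 2 (0.0588), and SCARB2 without SBI-0206965 replicate 3 (0.0744).

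Altogether 138 genes rose with both inhibitors and 216 fell with both, while 94 passed in both with opposite signs. Independent lists of these sizes would share 39.9 rising and 52.1 falling genes and 92.1 with opposite signs. In 50 simulations all 12 libraries were drawn without effect, and both groups shared the simulated controls. On average 148.2 genes had the same sign at an unadjusted limma-trend p under 0.05, a threshold chosen after seeing the data, and 1305 were observed. The simulations hold no changed genes, so they cannot show how many of the 1305 come from shared controls. With the DMSO libraries split into 2 pairs, 1 pair per inhibitor, 7 to 31 genes rose with both and 32 to 82 fell with both over the 6 splits, against 6.8 and 12.4 on average for independent lists. The covariance of the fold changes across genes was 0.0197, against 0.00894 simulated, and their correlation was 0.309, below the 0.500 of the simulations without effect (0.045 to 0.153 with split controls); genes are not independent replicates. With unscaled CPM, 213 rose and 151 fell with both. The count of 354 genes with the same sign fell to 196 without DMSO replicate 1, 191 without DMSO replicate 3, and 196, 200 and 204 without SBI-0206965 replicates 1, 2 and 3. It rose to 536 without DMSO replicate 4 and to 689 without all libraries numbered 4. The count of 94 with opposite signs fell to 52, 55 and 59 without DMSO replicates 1, 2 and 3 and to 58, 62 and 60 without SBI-0206965 replicates 1, 2 and 3, and was 162 without all libraries numbered 4.

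For the mean of both inhibitors against DMSO, 859 genes rose and 908 fell. THBS1 led the rises (1.99, adjusted p = 4.13e-10), carried by ULK101 alone since it fell with SBI-0206965 (-0.51, adjusted p = 0.00668). Ribosome biogenesis and MYC targets fell in 25 of 30 members and rose in 0 (27 and 0 adjusted over the list alone; camera, adjusted p = 2.41e-22, and 0.00258 with an estimated correlation). ERK feedback genes fell in 12 of 20 and rose in 1 (13 and 2 adjusted over the list alone; adjusted p = 1.94e-08, and 0.00258 with an estimated correlation). Cytosolic heat shock genes fell in 7 of 15 (9 adjusted over the list alone; adjusted p = 3.91e-06, and 0.0142 with an estimated correlation). ATF4 genes rose in 10 of 28 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 1.97e-05, and 0.0157 with an estimated correlation). JAK-STAT5 targets fell in 9 of 15 (9 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 8 of 19 (12 adjusted over the list alone, adjusted p = 0.0558 with an estimated correlation). G2/M genes fell in 4 of 24 (4 adjusted over the list alone, adjusted p = 0.164 with an estimated correlation). The ATF4 rise and the G2/M fall were carried by ULK101. With SBI-0206965, ATF4 genes fell in 5 and rose in 1, and G2/M genes fell in 0 and rose in 1. With ULK101 the ERK feedback list did not pass (camera, adjusted p = 0.359). Megakaryocyte genes fell in 4 of 19 and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0169, but adjusted p = 0.0717 with an estimated correlation, and 0.0612 without DMSO replicate 2 or 0.0602 without DMSO replicate 4). The authors' deposited table, named for control against both inhibitors, gives 339 genes up and 327 down at an adjusted p under 0.05. Of these 666, 662 also passed here with the same sign. Its values are not those of the mean taken here. AKAP12 has a log2 fold change of 2.19 there (edgeR, adjusted p = 0.157) and 0.65 here (limma-trend, adjusted p = 0.00351). The counts of the 2 are therefore not of like tests. With unscaled CPM 1190 rose and 656 fell, and with GC content and length trends removed 1253 rose and 1953 fell, both chosen after seeing the data. The count moved to 1123 without DMSO replicate 1, 1100 without DMSO replicate 3, and 2657 without the libraries numbered 4.

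The last comparison sets the inhibitors against each other at the same stated dose and time. ULK101 libraries exceeded SBI-0206965 libraries most in THBS1 (512.9 against 15.1 CPM, log2 difference 4.99, SE 0.103, adjusted p = 6.70e-16) and AKAP12 (172.1 against 4.89 CPM, 4.86, adjusted p = 2.27e-13). GBP5 (3.71), AQP2 (3.37), LIF (2.91), RDH10 (2.90), ARHGAP29 (2.89), GBP4 (2.89), DDIT4 (2.77) and WNT11 (2.68) followed. ULK101 was lowest against SBI-0206965 in ID3 (-2.81), SMAD6 (-1.67), APLNR (-1.39), EXOC3L4 (-1.37) and TUBB1 (-1.32). Smaller differences were the olfactory receptor OR2W3 (-1.16), the receptor kinase FGFR3 (-1.09), AQP1 (-1.06), the prostaglandin receptor PTGDR2 (-1.02) and the dynamin DNM3 (-1.01).

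ERK feedback genes were higher with ULK101 than with SBI-0206965 in 11 of 20 members and lower in 1 (11 and 1 adjusted over the list alone; camera, adjusted p = 5.10e-06, and 0.00412 with an estimated correlation). ETV5 differed by 2.39 and SPRY1 by 1.60. ATF4 and integrated stress response genes were higher in 24 of 28 and lower in 0 (25 and 0 adjusted over the list alone; adjusted p = 1.56e-20, and 0.000273 with an estimated correlation). G2/M genes were lower with ULK101 in 20 of 24 and higher in 0 (20 and 0 adjusted over the list alone; adjusted p = 5.39e-18, and 0.00412 with an estimated correlation), PLK1 by -0.82. Erythroid genes were lower in 17 of 28 and higher in 0 (18 and 0 adjusted over the list alone; adjusted p = 1.08e-09, and 0.0368 with an estimated correlation). SLC25A37 was at -0.54. Higher with ULK101 by the preset test were also NF-kB genes (7 of 17, 8 adjusted over the list alone; adjusted p = 0.0707 with an estimated correlation), secreted profibrotic factors (6 of 9, 6 adjusted over the list alone, with VEGFA at 1.21; adjusted p = 0.0602 with an estimated correlation) and chaperones of the endoplasmic reticulum (9 of 19, 10 adjusted over the list alone; adjusted p = 0.212 with an estimated correlation). Mitochondrially encoded mRNAs were lower by the preset test (1 of 13, 0 adjusted over the list alone; adjusted p = 0.707 with an estimated correlation). That last call was lost without SBI-0206965 replicate 1 (adjusted p = 0.139), SBI-0206965 replicate 2 (0.108), ULK101 replicate 3 (0.199) or ULK101 replicate 4 (0.321), and with fry (0.293). Ribosome biogenesis genes did not pass with camera (7 of 30 lower, 7 adjusted over the list alone, adjusted p = 0.107; fry, lower, 0.0266).

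**Figure D3:**
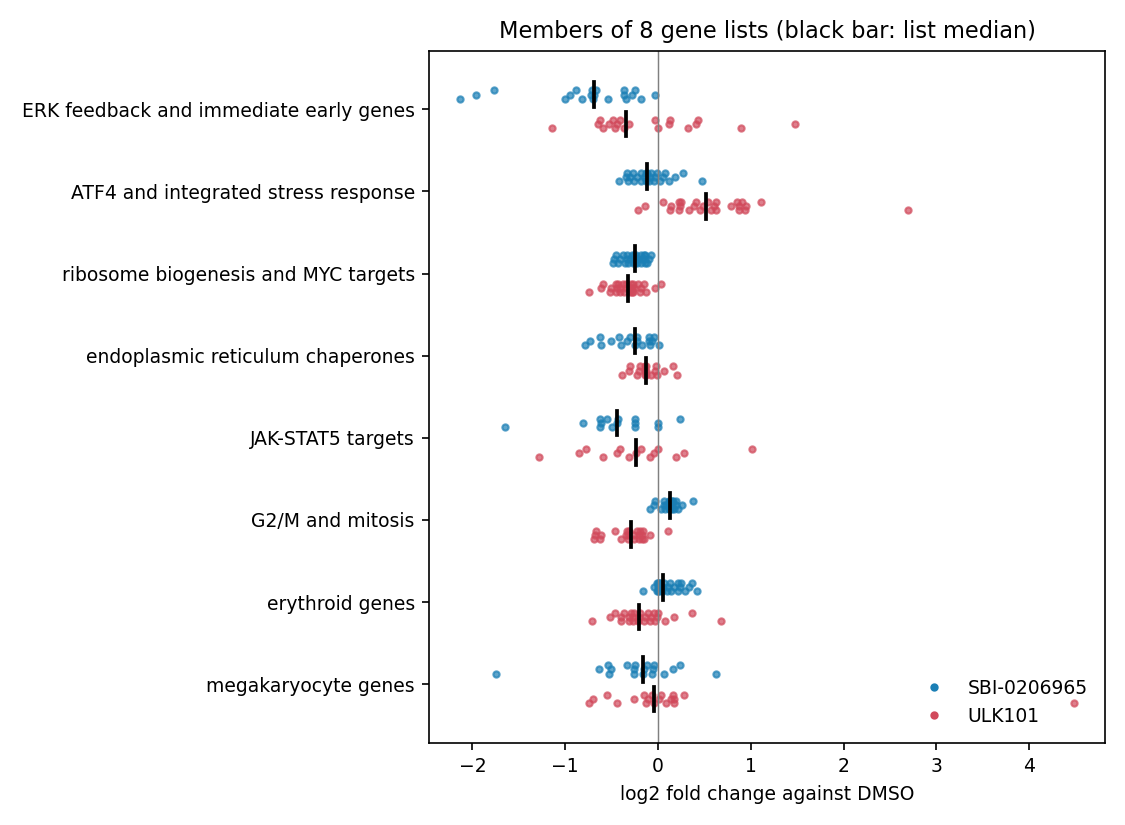
Log2 fold change against DMSO (x axis) of each measured member of 8 gene lists, for SBI-0206965 and ULK101, with the list median as a black bar. The ERK feedback list has a median of -0.69 with SBI-0206965 and -0.34 with ULK101, and the ATF4 list -0.12 and 0.51.

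Between the inhibitors 1333 genes were higher and 1224 lower with ULK101 (limma-trend, adjusted p under 0.05), and 135 and 12 of them differed at least 2-fold. With unscaled CPM 1586 were higher and 958 lower, and with GC content and length trends removed 1607 and 2503, both chosen after seeing the data. Without the libraries numbered 4 the counts were 1685 and 1722.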

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

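The tests of the libraries numbered 4, of unscaled CPM, of GC content and length and of shared DMSO libraries were chosen after seeing the data. Within groups of 4, the gap between a single library and the next, as a share of the range, was above Dixon's 95% critical value in 29 of the 345 groups of values examined. Of the 29, 8 fell on DMSO replicate 4 and 9 on SBI-0206965 replicate 4. Some groups pass a 95% critical value by chance. A flag can also arise because the other values nearly agree, as for PSAT1 in SBI-0206965 (69.2 to 69.4 CPM against 67.3). DMSO replicate 4 stood apart for GBP5 (2.08 CPM), HDAC11 (2.6), THBS1 (17.9), WNT11 (24.5), BCL2L1 (264.6), CTSB (202.8), NFE2 (386.3) and RELB (15.4). SBI-0206965 replicate 4 stood apart for FGFR3 (127 CPM), KAZN (37.3), SESN3 (28.8), UBASH3B (119.6), PIM2 (135.5), PSAT1 (67.3), ASAH1 (183.2) and BMP6 (3.87), and for its total of 59.7 M reads.

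Other single libraries that stood apart were ULK101 replicate 4 for ALAD (42.7 CPM) and UBASH3B (325.3), ULK101 replicate 3 for KAZN (23.5) and MYBBP1A (118.8), and ULK101 replicate 2 for GATA2 (587.4) and for 4.72% of its reads in the 10 most abundant genes. DMSO replicate 2 stood apart for GBP4 (63.0 CPM) and MYCN (7.14), DMSO replicate 1 for ASAH1 (172.1), and SBI-0206965 replicate 3 for PLVAP (27.2), SCARB2 (17.9) and EGR3 (0.0849).

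The libraries numbered 4 differed from the other 9 at 3834 genes (1816 higher and 2018 lower, limma-trend with a term for them beside the groups), while the same term for the libraries numbered 1, 2 or 3 called 0 genes each. Sequencing depth was tested by thinning every library to the lowest total, after which 3845 genes were called, so depth does not account for it. With each library's trend on GC content and gene length removed, 781 genes were left, and the term itself followed GC content across genes (Spearman 0.63, with -0.39 for length), which is consistent with a difference in library preparation or amplification. The design names no biological difference for these libraries, and none was tested.

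The 2 inhibitors moved 94 genes in opposite directions, 63 of them lower with SBI-0206965 and higher with ULK101, AKAP12, ETV5 and WNT11 among them. Scaling does not account for this, since 91 or more were left with unscaled CPM or median-of-ratios factors. Simulations without effect, with simulated controls shared by both groups, gave 0.7 genes with opposite signs on average at an unadjusted p under 0.05, where 292 were observed. But shared controls push both comparisons the same way, so the simulated number was fixed by the design and excludes nothing. Removing the trends on GC content and length gave 253. But both lists grew with it, from 936 to 2126 genes for SBI-0206965 and from 2855 to 4544 for ULK101. Longer lists share more genes by chance, so this rise does not decide whether such trends play a part. A difference in what the inhibitors act on beside ULK1 is a hypothesis that the libraries do not test. In the main fit 94 is close to the 92.1 of independent lists. With the replicate block 217 genes had opposite signs, but the lists held 2067 genes for SBI-0206965 and 4265 for ULK101. Without the libraries numbered 4 it was 162, from lists of 1545 and 3926. Independent lists of such lengths also share more genes, and their number was not computed. The 217 and 162 therefore show no excess of opposite changes.

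Chance as the source of the 4 comparisons was tested by other splits of the same libraries into groups of the same sizes, with only those libraries in the fit. For SBI-0206965 against DMSO 1 of 35 splits, the real one, gave as many genes (683), and the highest other gave 0. For ULK101 against DMSO it was 1 of 35 with 2424 genes, and the highest other split, which exchanged DMSO replicate 4 and ULK101 replicate 2, gave 1027. Between the inhibitors it was 1 of 35 with 2861 genes, and exchanging SBI-0206965 replicate 4 and ULK101 replicate 2 gave 482. For DMSO against both inhibitors pooled it was 1 of 100 drawn splits with 522 genes and 0 in the highest other. None of the other splits run gave as many genes in any of the 4.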

How the results depend on the processing

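The tests on recovered reads by edgeR, unscaled CPM, the libraries numbered 4 and GC content and length were chosen after seeing the data. Counts moved by over 1.5 times as follows, in the order SBI-0206965, ULK101, mean of both, ULK101 against SBI-0206965, same direction in both. A 2-fold minimum left 33, 116, 24, 147 and 1. A term for the libraries numbered 4 gave 2126, 4343, 3074, 3924 and 941, and GC content and length trends removed gave 2126, 4544, 3206, 4110 and 960. Without the libraries numbered 4, 1545 genes changed with SBI-0206965, 2657 with the mean of both and 689 the same way in both. DESeq2 gave 1411 for SBI-0206965 and 571 the same way in both. The 2-fold minimum leaves fewer genes by its construction; for the others the cause was not tested.

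Leaving out 1 library gave 557 to 1190 genes for SBI-0206965, 1100 to 2208 for the mean of both 191 to 536 in the same direction and 52 to 109 in opposite directions. Without a library the tests have fewer samples, but the counts rose without DMSO replicate 4.

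The replicate numbers did not pair the samples throughout: 7 of 12 same-numbered pairs had a correlation of deviations over 0.1 (-0.06 to 0.52), among them all pairs numbered 4 (0.52, 0.26 and 0.20) and 2 (0.12, 0.14 and 0.22), and 6 of 12 libraries were closest to their own number. Pairs with different numbers reached 0.24 (DMSO replicate 3 with ULK101 replicate 2), above every pair numbered 2. With the replicate block 2067, 4265, 3041 and 3866 genes were called in the 4 comparisons 913 the same way in both and 217 with opposite signs.

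With an estimated correlation 5, 3, 4 and 4 lists passed in the 4 comparisons in place of 14, 7, 8 and 8, and with fry 13, 13, 10 and 13 passed. For SBI-0206965 fry lost erythroid genes and HIF targets and added monocyte genes, and for the mean of both it added autophagy and lysosome. New with fry were autophagy, lysosome, p53, ERK, NF-kB and secreted factors for ULK101, and lysosome, heat shock, p53, ribosome biogenesis, megakaryocyte and monocyte genes between the inhibitors, where mitochondrially encoded mRNAs were lost. Of the 101 results on named genes, 32 alternatives lost the call (of ULK1, SHF, HDAC11, GFI1 and SCARB2), 2 gained it for ULK1 without the libraries numbered 4, and none reversed a direction. No low-count filter is the same as the main analysis, since the filter removed 0 genes, and for the mean of both the groups compared are all the groups. At the depths of 43597555 to 62495111 reads, genes changed 1.5-fold were recovered in 56.7% of 67 simulated cases for SBI-0206965. Fewer genes were changed there than passed in the real data.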

Other observations

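Of the tests below, those on low abundance, on GC content and length and on BMP targets were chosen after the results were seen. Pseudogenes, which no comparison above used as a group, were shifted upward after ULK101. Of 651 measured, 65 rose and 9 fell (limma-trend), against 1434 and 1421 of all 14520 genes, so it was the fewer falls that set them apart. Their median log2 change was 0.17 (bootstrap 95% interval over genes 0.15 to 0.19), against 0.03 after SBI-0206965. The sum of their CPM was 3790 to 4125 in the DMSO libraries, 4085 to 4234 with SBI-0206965 and 4115 to 5037 with ULK101. The lowest sum with ULK101, that of replicate 3, lay within the range of SBI-0206965 and also within that of DMSO, below DMSO replicate 2 (4125). Across all genes the change after ULK101 followed abundance: the median was 0.10 in the least abundant of 5 classes of 2904 genes and -0.08 in the most abundant.

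The pseudogene shift was tested against 3 explanations. Reads shared with parent genes do not account for it in the 282 of 651 pseudogenes that were paired with a parent. These changed by 0.21 more than their parents (median difference, interval over genes 0.14 to 0.29). The parents had a median of -0.06, and the changes of pseudogene and parent had a Spearman correlation of 0.06. The other pseudogenes were not covered by this test. Protein coding genes matched on abundance had a median of 0.09 (95% of 10000 lists between 0.07 and 0.12), below the 0.17 of the pseudogenes, so low abundance may account for about that much and not for the rest. With the trends on GC content and length removed the median was 0.13, between the bounds first set for it, but that of all genes moved too, from 0.01 to -0.03. The difference from all genes, examined for that reason, was 0.16 before and 0.15 after (interval over genes 0.13 to 0.18), which argues against such a trend as the whole cause.

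Genes raised by ULK101 lay next to each other more often than by chance. Of 14489 neighbouring pairs, 234 had both genes raised, against a median of 141 in 10000 permutations of the calls (p = 1e-04, the smallest they can give). Among pairs that do not overlap the number was 180 against 113, and with the trends on GC content and length removed 246 against 161. The guanylate-binding protein genes GBP4 and GBP5, at 89181148 to 89198932 and 89258950 to 89272804 on chromosome 1, are such a pair, with log2 changes of 2.48 and 3.10. Of genes lowered by ULK101 there were 201 such pairs (139 in permutations), of genes lowered by SBI-0206965 there were 51 (19 in permutations), and of genes raised by it 16 (11 in permutations, p = 0.1).

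ID1, ID2, ID3 and SMAD6, which fell after ULK101, are BMP target genes. With SBI-0206965 ID1 (-0.63, limma-trend, adjusted p = 0.000139) and ID2 (-0.35, adjusted p = 0.0272) fell as well. ID3 (-0.085, adjusted p = 0.808) and SMAD6 (0.054, adjusted p = 0.868) did not pass there. A list of 26 BMP targets and pathway genes was written after the falls with ULK101 were seen. The other 11 measured members had a median change of -0.06 after ULK101, at the 11.4th percentile of 10000 lists matched on abundance, and members went both ways, so a common change outside the 4 genes stays open. BMP6 (-0.50, adjusted p = 0.0287) and GATA2 (-0.26, adjusted p = 0.0249) fell, and HEY1 (1.48, adjusted p = 6.19e-06) and FST (0.46, adjusted p = 0.0244) rose. HEY1 was near the floor in DMSO, at 0.36 to 0.61 CPM.

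GBP4 and GBP5 are also known as interferon-induced genes. The interferon response list did not pass after ULK101 (1 of 22 up, STAT2 at 0.43, and 2 down; camera, adjusted p = 0.735).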
